A study of Mus musculus with 10 samples.

How the data were processed

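Total RNA came from the synovium of the left hind leg of 10 mice, which per the labels' protocols was freed of surrounding muscle and skin. Biotin-labelled cRNA made from 100 ng of RNA was hybridised to Affymetrix mouse genome arrays, which carry probe sets near the 3' ends of transcripts. Group and replicate number come from the sample titles, with 5 biological replicates per group. The labels give no scan date or other batch.

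The deposited value of a probe set is named a score here, because its scale could not be settled from the sources. Per the submitters' processing notes R 3.2.1 was used, and the background correction, normalization and summary method are not given in the sources used here. The values have 6 decimals, and rounding is close to the spread between arrays for many probe sets. Of 39993 probe sets, 225 held 1 value on all arrays, 8800 held 5 or fewer distinct values, and 13104 held 10. The design had foreseen log2 values. The tests were run on the deposited scores as they stand, and Hedges' g per probe set does not depend on a linear scale of its own. The moderated test does, through the variance prior that probe sets share. What the authors' method did to differences between arrays can change the relation between probe sets of large and small spread, and with it principal components and rank products. No probe set was left out of the main test, and the table given here held no control probe sets of the array maker. All per-sample columns were used.

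Probe sets were named from the platform annotation. In it 34202 named 1 gene, 931 named several and were not used for genes, and 4860 were unnamed here. The Entrez identifier of 34027 of 34200 was found in the RefSeq gene table, which changed 0 symbols. One probe set stood for each of 18127 genes, the one with the highest mean among those naming that gene alone. Genes of the lists without such a probe set are not part of the counts; older symbols were matched through synonyms.

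The comparison was maslinic acid against vehicle, all 10 arrays, no covariate, with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The prior degrees of freedom were 0.503, so that variances were hardly shared between probe sets. Gene lists, 18 pathway lists and 14 cell type marker lists, were tested with camera at an inter-gene correlation of 0.01 and adjusted over all 32. Alternatives for lists were an estimated correlation, fry, which tests whether genes of a list move on balance one way without comparing them with other genes, and an exact permutation of the mean z-score per array. Tests of single values used all 252 assignments of 10 arrays to 5 and 5. Where such a test had a covariate, the covariate stayed with its array. Those p-values are approximate when the covariate differs between groups. Tests with arrays left out used all assignments of those that remained, 56 without vehicle replicates 3 and 5. Correlations used 100000 permutations. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

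The genes named were set by a rule, 93 in all, of which those in lists that did not pass are mostly left to the counts. They were the 12 of lowest p in each direction (since none passed, and with 1 clone-named gene skipped), the 2 members of lowest p in each list, and Il1b, Il6, Tnf, Ptgs2, Mmp3, Mmp13, Col1a1, Col2a1, Acan and Nr3c1. The groups, tests, lists, this rule and most alternatives were set before the data were examined. The alternatives were the replicate number as a block, a filter at the median level, quantile normalization, centring on array medians, trended and robust eBayes, array weights, a muscle covariate, other thresholds, the rank product over 25 pairs of arrays, the exact Wilcoxon test, the mean of all probe sets of a gene and each array left out. A filter on 10 distinct values, the array permutation of lists, scaled components, leaving out vehicle replicates 3 and 5, a neutrophil covariate, genes held by 1 list alone and the probe set with the most distinct values were added after seeing the data.

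The scripts were tested on simulated data of this comparison with 39993 probe sets, 50 of them changed at each size. The changed ones were drawn only from probe sets with 10 distinct values, and the simulated noise was independent between probe sets. limma recovered 10% at a shift of 2 SD, 64% at 4 SD, 96% at 6 SD and 100% at 8 SD, with 3 false calls. Differences of 2 SD were thus mostly out of reach with 5 arrays per group, and no size between 2 SD and 4 SD was simulated. Recovery for probe sets with fewer distinct values was not simulated. With 18127 genes, a list of 20 genes shifted by 1 SD gave camera adjusted p = 2.48e-08 at the preset correlation and 0.00483 at the estimated one, with 0 of 31 other lists called; these simulated genes were uncorrelated. The rank product recovered 126 of 200 changed probe sets with 932 false calls. No 2 arrays were alike: correlations of z-scores between arrays ran from -0.52 to 0.40, and 0 columns were identical.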

Results

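Gene expression was measured in the synovium of 10 male DBA/1J mice with collagen antibody-induced arthritis (CAIA). In this model an antibody against type II collagen, followed by bacterial lipopolysaccharide, causes joint inflammation within days. All mice received 1 mg of antibody on day 8 and 25 µg of lipopolysaccharide on day 11, and tissue was taken on day 12. The vehicle group (5 mice) was given corn oil by mouth. The maslinic acid group (5 mice) was given the olive-derived triterpene maslinic acid in corn oil every day, at 200 mg per kg of body weight. The mice were bought at 5 weeks of age and are labelled as 8 weeks old. The submitters' design text says that the 5 mice per group were selected from larger groups, without giving the criterion, and it also describes untreated mice, which were not analysed here. Each mouse gave 1 Affymetrix mouse genome array, so the number of arrays limits the precision.

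The median value of a probe set was 6.74. Such levels look like log2 intensities, but differences between arrays were very small. The median SD of a probe set over the 10 arrays was 6.68e-06, 93.5% of probe sets had a range under 0.001, and the largest range was 0.989. A difference between groups is therefore not a log2 fold change, and its scale is unknown. Differences are given below as Hedges' g, the difference maslinic acid minus vehicle in units of the SD within groups, with its 95% confidence interval and n = 5 per group. This measure is the same under any linear rescaling of a probe set.

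The first question was whether treatment or something else carried most of the variation between arrays. In the deposited units, whose scale is unknown, it was carried by a few inflammation and muscle genes that varied between mice of both groups. The first principal component over 18127 genes took 70.1% of the variance. Its leading genes were Saa1, an acute-phase protein (20.4% of the component), Mmp3, the matrix-degrading enzyme stromelysin 1 (17.8%), Myh1, a fast muscle myosin (14.6%), and Ccl7, a monocyte-attracting chemokine (10.5%). Saa1, Mmp3 and Ccl7 varied opposite to Myh1. No group difference was detected on this component (exact permutation p = 0.960, two-sided, over all assignments of the arrays to the groups). The second component, with 12.5% of the variance, was lower in the maslinic acid group (exact p = 0.0238, and 0.0714 adjusted over 3 components), and the third, with 6.73%, gave an exact p of 0.476. Over the 6743 genes with 10 distinct values, each scaled to unit SD, the first component took 40.3% and gave an exact p of 0.190, and the second took 19.7% and gave an exact p of 0.349. Vehicle replicates 3 and 5 dominated that scaled first component, with scores of 77.4 and 106 against -43.3 to 20.9 for the other arrays.

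Vehicle replicates 3 and 5 stood apart from the other arrays. Their array quality weights in limma were 0.244 and 0.198, against 0.696 to 3.85 for the other arrays. The mean distance between arrays was 1.56 among vehicle mice and 1.08 among maslinic acid mice, in SDs per gene over the 6743 genes with 10 distinct values. This difference lay within what reassigning the arrays gave (exact permutation p = 0.278). Of these genes, 81.7% had a larger SD in the vehicle group.

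**Figure D1:**
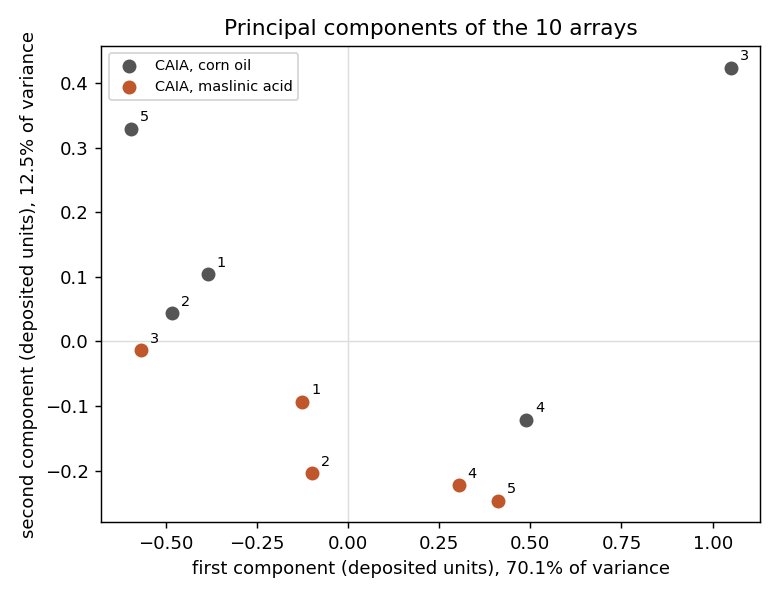
Scores of the 10 arrays on the first component (x axis, deposited units, 70.1% of variance) and the second (y axis, deposited units, 12.5% of variance), with each point's replicate number. Both groups spread along the first component, and vehicle replicates 3 and 5 lie highest on the second.

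The main comparison asked which genes differ between arthritic mice with and without maslinic acid. No gene and no probe set passed the test. Of all probe sets of the table, 0 had an adjusted p under 0.05 in limma (lowest adjusted p = 0.148). At an unadjusted p under 0.05 there were 3617 probe sets, 9.04% against 5% on average by chance, of which 1506 were higher and 2111 lower with maslinic acid. Chance is not excluded for this count, as 9 of 100 splits of the arrays into 5 and 5, the real one included, gave at least as many. The exact Wilcoxon test gave 0 probe sets after adjustment and 2741 at an unadjusted p under 0.05. Its smallest p is 0.00794, so a pass needed far more than 2741 probe sets at such p-values. That 0 therefore does not test single probe sets. The rank product gave 1576 probe sets, but on simulated data it also made 932 false calls. The values of the groups did not overlap in 544 probe sets, 1.36% against 0.794% on average by chance, and this count was not compared with other splits. At the level of genes, 0 of 18127 passed (lowest adjusted p = 0.461). Unadjusted p-values under 0.05 were found for 1552 genes, 765 higher and 787 lower.

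None of the 24 genes of lowest p in either direction passed, at an adjusted p of 0.461 each, although their groups did not overlap. The exact permutation p of each was 0.00794, the smallest that 5 against 5 arrays can give. The 12 with higher values had g between 2.83 and 4.85. They included Srprb, a subunit of the signal recognition particle receptor (g = 4.85, 95% CI 2.25 to 7.42), Rc3h1, the mRNA-binding protein roquin-1 (3.47, 1.43 to 5.45), Smad4, the shared mediator of TGF-beta and BMP signals (3.23, 1.28 to 5.11), and Per1, a clock gene that glucocorticoids also induce (2.85, 1.04 to 4.58). The others were Tob2, Eml1, Slc38a2, Sec23a, Abl2, Atp7a, Zscan21 and Vnn1. The 12 with lower values had g between -4.38 and -2.86. They included Fut7, the fucosyltransferase that makes selectin ligands on leukocytes (-3.31, -5.22 to -1.33), F10, coagulation factor X (-2.87, -4.62 to -1.06), and Cep55, a cytokinesis protein (-2.90, -4.65 to -1.08). The others were Zfp688, Majin, Paqr5, Cyrib, Snx20, Snhg7, Tmem160, Emb and Unc119. Values have 6 decimals, so some of these g rest on a few rounding steps. Srprb differed by 7.6e-06 (SDs 1.64e-06 and 1.14e-06, 8 distinct values) and Majin by -4.2e-06 (5 distinct values). Without single arrays Rc3h1 ran from 3.15 to 5.94, Cyrib from -7.30 to -2.97 and Majin from -7.83 to -4.00. The genes were picked by their p-values, and the intervals do not allow for that choice. When each array was centred on its own median, 8 of the 12 higher genes turned to the other direction (Srprb, Rc3h1, Smad4, Eml1, Slc38a2, Sec23a, Abl2 and Atp7a). After quantile normalization Srprb, Rc3h1, Smad4, Slc38a2, Sec23a, Atp7a, Zscan21, Majin and Paqr5 turned, and Fut7 was at 0.

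Gene lists fixed beforehand asked whether pathways or cell types moved together. Of 32 lists, 15 passed camera's threshold of an adjusted p of 0.05 with its preset inter-gene correlation of 0.01. Of these, 11 were higher and 4 lower with maslinic acid. With a correlation estimated from the arrays, 0 lists passed, and 0 passed in fry, so the calls below rest on the preset correlation. The estimates for the 15 lists were all above it. They ran from 0.018 (bile acid receptor, PPAR and lipid uptake) to 0.63 (platelets), with 0.56 for muscle, 0.42 for collagens and matrix and 0.29 for glucocorticoid receptor targets. Members of such lists move together, so a count of members in 1 direction is not a count of independent genes. The exact permutation of arrays gave 0 as well, with 4 lists at an unadjusted p under 0.05. Its smallest p is 0.00794. A pass thus needed at least 6 lists at that p, or a larger number of lists at somewhat larger p. Without vehicle replicates 3 and 5, 11 of the 15 kept call and direction and 1 other list passed; after quantile normalization 8 of the 15 did and 3 others passed.

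**Figure D2:**
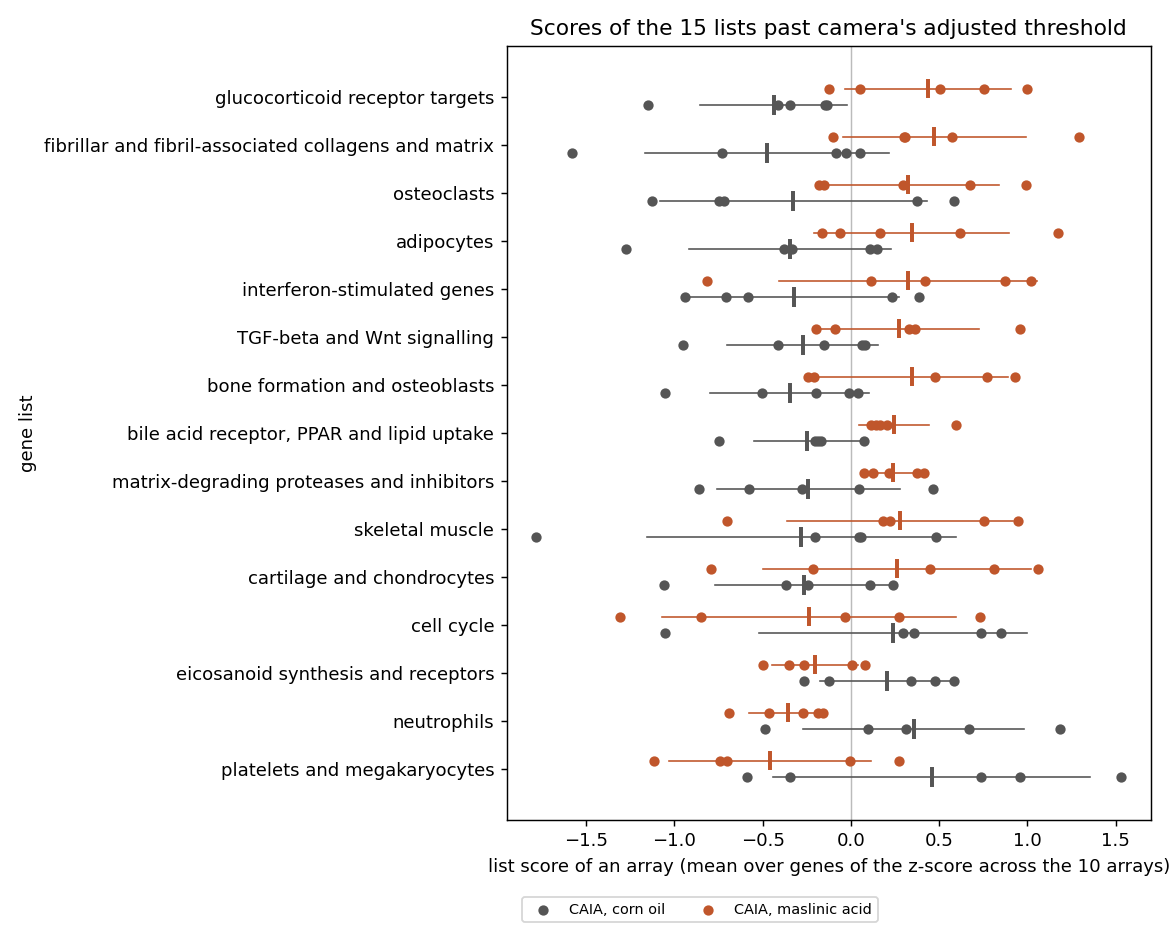
Score of each array for the 15 lists that passed camera (x axis: mean z-score over the genes of a list, in SDs; y axis: list). Points are arrays, vertical bars group means and horizontal lines 1 SD to each side; scores of both groups overlap in every list except the glucocorticoid receptor targets and the bile acid receptor, PPAR and lipid uptake list, whose maslinic acid arrays come close to the highest vehicle array.

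Genes of connective tissue matrix and bone were higher with maslinic acid. The share of bone, cartilage, muscle or fat in each dissected sample was not measured. All 30 measured members of the list of fibrillar and fibril-associated collagens and matrix had higher means (median g = 0.99, camera adjusted p = 3.48e-09; adjusted p = 0.340 with an estimated correlation). Of these, 5 reached an unadjusted p under 0.05 and 0 passed after adjustment over the list alone or over all genes. Examples are Tnc, tenascin C (g = 1.76, 95% CI 0.32 to 3.13), Col16a1 (1.59, 0.20 to 2.91) and Col1a1, the main collagen of bone and tendon (0.95, -0.29 to 2.13). The mean list score was -0.474 ± 0.693 in vehicle and 0.474 ± 0.516 in maslinic acid mice (SD, n = 5 each; exact permutation p = 0.0317, adjusted p = 0.305). Bone formation genes were higher in 15 of 16 (median g = 0.61, adjusted p = 0.00217; adjusted p = 0.340 with an estimated correlation), among them Ibsp, bone sialoprotein (1.46, 0.11 to 2.75), and Sp7, the osteoblast transcription factor osterix (1.18, -0.11 to 2.41). Osteoclast genes were higher in 12 of 14 (0.82, adjusted p = 0.00357; adjusted p = 0.376 with an estimated correlation), with Acp5, tartrate-resistant acid phosphatase, at 1.41 (0.07 to 2.68) and Nfatc1 at 1.26 (-0.04 to 2.51). Cartilage genes were higher in 23 of 25 (0.49, adjusted p = 0.00357; adjusted p = 0.422 with an estimated correlation), with Ucma at 1.83 (0.37 to 3.22), Sox9 at 1.53 (0.15 to 2.83), Col2a1 at 0.61 (-0.56 to 1.75) and Acan at 0.62 (-0.55 to 1.76). Without single arrays Sox9 ran from 1.31 to 3.58, Col2a1 from 0.29 to 1.15 and Acan from 0.33 to 1.39. The cartilage call was lost without vehicle replicate 5 (median g = 0.28, adjusted p = 0.0503) and without maslinic acid replicate 1 (0.36, adjusted p = 0.0920). The list's median was 0.81 without maslinic acid replicate 2. Without vehicle replicates 3 and 5 together, neither cartilage (0.20, adjusted p = 0.0833) nor osteoclast genes (0.45, adjusted p = 0.163) passed; after quantile normalization osteoclast genes did not pass (0.38, adjusted p = 0.154) and Sox9 was at -0.10.

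TGF-beta and Wnt signalling genes were higher in 30 of 35 (median g = 0.65, adjusted p = 0.000372; adjusted p = 0.340 with an estimated correlation). After adjustment over the list alone 1 passed, Smad4, and over all genes 0 did. Fzd4, a Wnt receptor, had g = 2.18 (95% CI 0.61 to 3.68), and ran from 1.94 to 4.17 without single arrays. After quantile normalization the list's median was -0.12 (adjusted p = 0.200), with Smad4 at -0.57 and Fzd4 at -0.63, and with arrays centred on their medians Smad4 was at -0.12 and the list's median at -0.15 while its test pointed higher (adjusted p = 1.23e-05). Matrix-degrading proteases and their inhibitors were higher in 19 of 26 (0.57, adjusted p = 0.00391; adjusted p = 0.340 with an estimated correlation), and the median was 0.88 without vehicle replicate 4. Members went both ways. Adamts12 was at 2.00 (0.49 to 3.45), collagenase 3, Mmp13, at 1.03 (-0.22 to 2.22), and stromelysin Mmp3 at 0.13 (-0.99 to 1.25), while the urokinase gene Plau, with 6 distinct values over 10 arrays, was at -2.12 (-3.61 to -0.57). None of the 26 passed after adjustment over the list alone. The protease call was lost with array weights (median g = 0.30, adjusted p = 0.0554), with the neutrophil score as a covariate (0.67, adjusted p = 0.108) and without vehicle replicates 3 and 5 (0.34, adjusted p = 0.211); in these 3 settings Mmp3 was at -0.37, -0.52 and -0.20.

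Known targets of the glucocorticoid receptor had the largest median difference of the 32 lists, and were higher with maslinic acid in 18 of 20 (median g = 1.26, camera adjusted p = 1.23e-06; adjusted p = 0.340 with an estimated correlation). At an unadjusted p under 0.05 there were 10 higher and 1 lower, and 3 passed after adjustment over the list alone but 0 over all genes. These 3 were Per1, Zbtb16, a transcription factor strongly induced by glucocorticoids (g = 2.02, 95% CI 0.50 to 3.47), and Klf9 (1.94, 0.45 to 3.37). The 2 members with lower values were Hsd11b1, which regenerates active glucocorticoid (-1.59, -2.91 to -0.20), and Anxa1, annexin A1 (-1.15, -2.37 to 0.13). Klf9, Hsd11b1 and Anxa1 are named after their values were seen. The list also holds Nr3c1, the receptor itself, which counts among the 18 higher members at 0.12 (-1.01 to 1.24). Nr3c1 was at -0.47 after quantile normalization, -0.18 with arrays centred on their medians and -0.10 as the mean of its probe sets. The list score was -0.438 ± 0.415 in vehicle and 0.438 ± 0.468 in maslinic acid mice, and every maslinic acid array lay above every vehicle array (exact permutation p = 0.00794, adjusted p = 0.127).

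Genes of the bile acid receptor, PPAR and lipid uptake list were higher in 13 of 16 (median g = 0.57, adjusted p = 0.0270; adjusted p = 0.340 with an estimated correlation), although 0 members reached an unadjusted p under 0.05. Ppargc1a, a coactivator of mitochondrial and lipid genes, was at 1.20 (95% CI -0.09 to 2.43) and Scd1, stearoyl-CoA desaturase, at 1.16 (-0.12 to 2.39). Here too the array scores of the groups did not overlap (exact permutation p = 0.00794, adjusted p = 0.127). The camera call was lost without vehicle replicate 1 (adjusted p = 0.0543), vehicle replicate 5 (0.156) or maslinic acid replicate 2 (0.0544). It was also lost with the replicate number as a block (median g = 0.51, adjusted p = 0.0583), above the median level (0.75, adjusted p = 0.136), with array weights (0.47, adjusted p = 0.172), over genes with 10 distinct values (0.76, adjusted p = 0.0516), with the neutrophil covariate (0.65, adjusted p = 0.109) and without vehicle replicates 3 and 5 (0.53, adjusted p = 0.240), while the median stayed within 1.5 times its value in each. Interferon-stimulated genes were higher in 25 of 27 (median g = 0.70, adjusted p = 0.000372; adjusted p = 0.376 with an estimated correlation), with the GTPases Irgm1 at 1.35 (0.02 to 2.61) and Gbp2 at 1.27 (-0.03 to 2.52). None of the interferon-stimulated genes passed after adjustment over the list alone. After quantile normalization this list did not pass (median g = 0.27, adjusted p = 0.0738) and Irgm1 was at -1.13.

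Neutrophil and platelet markers were lower with maslinic acid. Neutrophil markers were lower in 12 of 13 (median g = -0.57, adjusted p = 0.00357; adjusted p = 0.340 with an estimated correlation), and 7 of the 13 also stand in other lists. Cxcr2, the receptor for neutrophil-attracting chemokines, passed after adjustment over the list alone (g = -2.71, 95% CI -4.39 to -0.96), and 0 passed over all genes. Csf3r, the receptor for the neutrophil growth factor G-CSF, was at -1.89 (-3.30 to -0.41). The median was -1.30 without vehicle replicate 5 and -0.94 without vehicle replicate 1. The list score was 0.355 ± 0.627 in vehicle and -0.355 ± 0.222 in maslinic acid mice (exact permutation p = 0.0476, adjusted p = 0.305). All 8 platelet and megakaryocyte markers were lower (median g = -0.98, adjusted p = 0.00217; adjusted p = 0.376 with an estimated correlation), with the platelet chemokines Ppbp at -1.62 (-2.96 to -0.22) and Pf4 at -1.48 (-2.77 to -0.12). None of the 8 passed over the list alone. After quantile normalization neither list passed: neutrophil markers had a median of -0.39 with the test pointing higher (adjusted p = 0.71), and platelet markers one of -0.57 (adjusted p = 0.154); with the neutrophil score as a covariate platelet markers were at 0.17. Eicosanoid synthesis and receptor genes were lower in 16 of 26 (median g = -0.56, adjusted p = 0.0190; adjusted p = 0.340 with an estimated correlation). Pla2g4a, the phospholipase that releases arachidonic acid, was at -1.85 (-3.24 to -0.38), the prostaglandin E2 receptor Ptger2 at -1.76 (-3.13 to -0.32), and Ptgs2, cyclooxygenase-2, at -0.62 (-1.76 to 0.55). Without single arrays Pla2g4a ran from -3.67 to -1.62, Ptger2 from -2.75 to -1.53 and Ptgs2 from -1.49 to -0.323. None of the 26 passed over the list alone. The eicosanoid call was lost without vehicle replicate 1 (adjusted p = 0.0508), vehicle replicate 2 (median g = -0.37, adjusted p = 0.0873) or maslinic acid replicate 5 (0.0719). It was also lost after quantile normalization, with a median of -0.23 (adjusted p = 0.371, Ptger2 at 0.01), and with the neutrophil covariate, with a median of -0.03 (adjusted p = 0.662). With the muscle covariate the median was -0.38 (adjusted p = 0.0978). The call was lost with little change in the median after median centring (-0.55, adjusted p = 0.0570), with the mean of probe sets (-0.56, adjusted p = 0.0660) and with the most distinct values (-0.56, adjusted p = 0.0826).

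**Figure D3:**
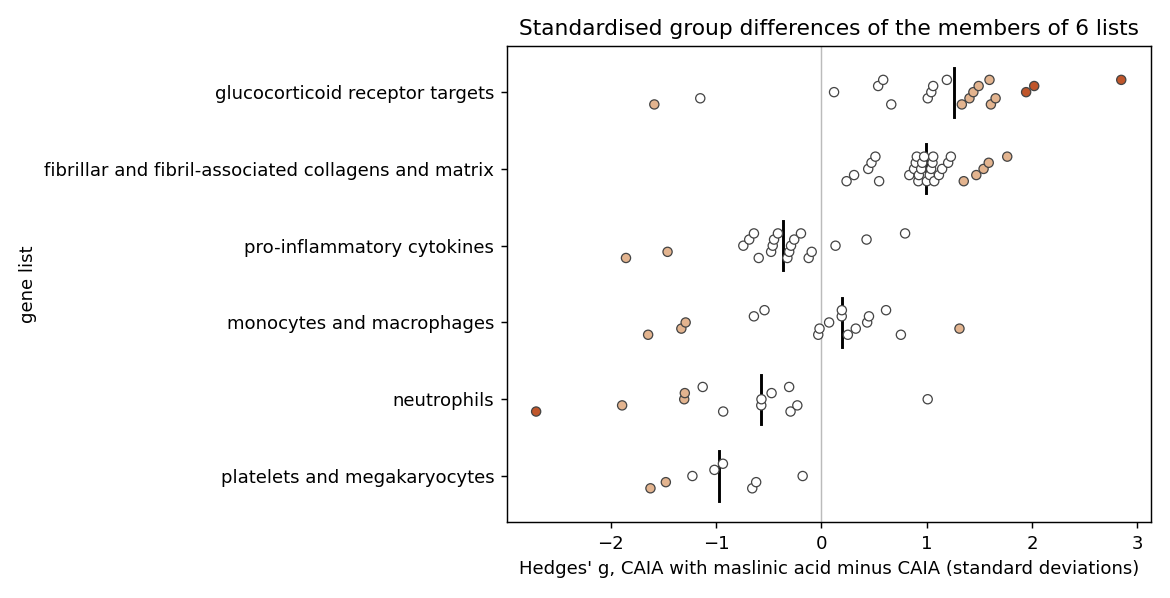
Hedges' g of each member (x axis, in SDs, maslinic acid minus vehicle) of 6 lists (y axis); the vertical bar is the median. Dark points passed after adjustment over the list alone, light brown points had an unadjusted p under 0.05, and open points had neither; all 30 collagen and matrix genes lie above 0 and all 8 platelet markers below it.

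Inflammatory cytokines and macrophage markers did not pass, although cytokines lay close to the threshold. The cytokine list also held Il1rn, the interleukin-1 receptor antagonist, so not every member is pro-inflammatory. Pro-inflammatory cytokines had lower means in 17 of 20 (median g = -0.37, adjusted p = 0.0523), with Il1b at -0.60 (95% CI -1.73 to 0.58), Il6 at -0.48 (-1.61 to 0.68) and Tnf at -0.45 (-1.58 to 0.70). These intervals include shifts of more than 1 SD in the lower direction, so such a fall is not excluded. Without single arrays Il1b ranged from -0.894 to -0.234, Il6 from -0.730 to -0.0561 and Tnf from -1.31 to -0.169; Il1b and Il6 were closest to 0 without vehicle replicate 5 and Tnf without vehicle replicate 2. The cytokine list passed, its test pointing lower, without vehicle replicate 1 (adjusted p = 0.0491), 3 (0.00588) or 4 (0.0185), and without maslinic acid replicate 1 (0.0359) or 3 (0.0397). It also passed above the median level (0.0411), over genes with 10 distinct values (0.0367), over unshared genes (0.0465) and with the neutrophil covariate (median g = -0.81, adjusted p = 0.00267). Its median without single arrays ran from -0.586 to -0.101.

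Other inflammation and immune cell lists did not pass either. Toll-like receptor and NF-kB signalling genes had a median g of 0.31 (adjusted p = 0.0545), chemokines of 4.39e-05 (0.615, the test pointing lower), and acute-phase and antimicrobial proteins of -0.03 (0.994). The Toll-like receptor list passed, its test pointing higher, without vehicle replicate 1 (adjusted p = 0.0491) or 2 (0.0116), without maslinic acid replicate 4 (0.0351) or 5 (0.0223), with the muscle covariate (median g = 0.65, adjusted p = 0.00422) and after quantile normalization (0.12, adjusted p = 0.0271). It passed too with the mean of probe sets (0.0400), the most distinct values (0.0321) and unshared genes (0.0465), and after median centring its median was -0.18 while the test pointed higher (adjusted p = 1.33e-05). Chemokines passed lower with the neutrophil covariate (-0.69, adjusted p = 0.0138). Acute-phase proteins passed after quantile normalization (0.34, adjusted p = 0.0178) and after median centring (-0.06, adjusted p = 0.0236), the test pointing higher in both. Monocyte and macrophage markers had a median of 0.19 while the test pointed lower (0.911). B and plasma cell markers were at -0.50 (0.0780), T and NK cell markers at -0.27 (0.237) and mast cell markers at -0.02 (0.141). B cell markers passed lower without vehicle replicate 4 (0.00989), without maslinic acid replicate 4 (0.0243) and with array weights (0.0412), T and NK cell markers without maslinic acid replicate 4 (0.0433), and mast cell markers above the median level (0.0402) and with array weights (0.00739). In these last lists Cd4 (g = -2.35, -3.91 to -0.73; 7 distinct values) and Ms4a2, a chain of the IgE receptor (-2.22, -3.74 to -0.64), passed after adjustment over their list alone, and neither passed over all genes.

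Cell cycle genes were lower with maslinic acid, and markers of muscle and fat were higher. Of 30 cell cycle genes, 23 were lower (median g = -0.40, adjusted p = 0.00357; adjusted p = 0.467 with an estimated correlation), with Pcna at -1.93 (95% CI -3.34 to -0.44) and Bub1 at -1.90 (-3.32 to -0.42). This call was lost without maslinic acid replicate 2 (median g = -0.11, adjusted p = 0.220). Its median was -0.23 without vehicle replicate 1 or maslinic acid replicate 3, -0.18 without vehicle replicate 3, -0.84 without vehicle replicate 5 and -0.67 without maslinic acid replicate 1. After quantile normalization it was -0.52 and did not pass (adjusted p = 0.0792), and with the neutrophil covariate it was 0.70. All 25 skeletal muscle markers had higher means (median g = 0.50, adjusted p = 0.00342; adjusted p = 0.467 with an estimated correlation), with Neb, nebulin, at 0.94 (-0.29 to 2.12) and Pygm at 0.93 (-0.30 to 2.11). The muscle call was lost without vehicle replicate 2 (0.28, adjusted p = 0.296) or maslinic acid replicate 2 (0.32, adjusted p = 0.0751), and the median was 0.32 without maslinic acid replicate 4. With the neutrophil covariate neither muscle (0.23, adjusted p = 0.521) nor adipocyte markers (0.43, adjusted p = 0.432) passed. Adipocyte markers were higher in 11 of 12 (0.80, adjusted p = 0.00357; adjusted p = 0.376 with an estimated correlation), with the lipase gene Pnpla2 at 1.57 (0.18 to 2.88) and Plin4 at 1.29 (-0.02 to 2.54). The adipocyte call was lost without vehicle replicate 2 (0.55, adjusted p = 0.0874). In none of these lists did a member pass over the list alone.

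The remaining lists did not pass. Tendon markers had a median g of 0.49 (adjusted p = 0.0733), endothelium of 0.27 (0.0614), synovial fibroblasts of 0.32 (0.137), erythroid cells of 0.15 (0.612), Schwann cells and nerve of -0.23 (0.671), and skin keratinocytes and hair of 0 (0.911). Circadian clock genes were at 0.01 (0.260), with Per1 the only member to pass over the list alone, oxidative phosphorylation at 0.08 (0.500), and Nrf2 and oxidative stress genes at 0.18 (0.599). Some of these passed under other settings. Tendon markers passed higher after quantile normalization (adjusted p = 0.00300), after median centring (3.22e-07), without vehicle replicate 1 (0.0491) and without maslinic acid replicate 4 (median g = 0.84, adjusted p = 0.00857). Endothelial markers passed higher without vehicle replicate 1 (0.0491) or 2 (0.64, adjusted p = 0.0116), with the muscle covariate (0.62, adjusted p = 0.0119), the mean of probe sets (0.0416), the most distinct values (0.0388) and unshared genes (0.0462). Erythroid markers passed higher with the neutrophil covariate (1.76, adjusted p = 0.00141) and after median centring (0.0184), and synovial fibroblast markers with the muscle covariate (0.0333) and after median centring (4.85e-05). Oxidative phosphorylation genes passed higher with array weights (0.47, adjusted p = 0.00528), without vehicle replicates 3 and 5 (0.0301) and without maslinic acid replicate 3 (0.0104). After median centring endothelium (-0.16, adjusted p = 0.000116), clock (-0.37, adjusted p = 0.00181) and Nrf2 genes (-0.32, adjusted p = 0.0236) had medians below 0 while their tests pointed higher and passed.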

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

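The tests of explanations below were chosen after the results they address had been seen; the search for single arrays far from their own group was set beforehand. In that search the gap between the highest or lowest array and its neighbour was divided by the range of the 5 arrays of a group. Of 205 groups tested, 14 had a ratio above the 95% critical value, where about 1 in 20 by chance, or 10.2, would.

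Vehicle replicate 3 had the lowest mean of all probe sets (ratio 0.929), the lowest median (0.725) and the lowest score for glucocorticoid receptor targets (0.726). Vehicle replicate 5 was highest for Ptgs2 (0.762) and Plau (0.75), and vehicle replicate 2 lowest for Neb (0.788). Maslinic acid replicate 2 was highest for Pla2g4a (0.912) and lowest for Snx20 (0.857), Cd4 (0.8) and Col1a1 (0.725). Maslinic acid replicate 3 was highest for the bile acid receptor, PPAR and lipid uptake score (0.807) and for Ptgs2 (0.725). Maslinic acid replicate 1 was highest for Il6 (0.720) and maslinic acid replicate 4 for Tob2 (0.789).

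The mean score of 6 connective tissue lists (collagens, cartilage, bone, osteoclasts, TGF-beta and Wnt, proteases) was 0.641 (SE 0.250) higher with maslinic acid (exact permutation p = 0.0238), and that of neutrophils and platelets differed by -0.814 (SE 0.370, exact permutation p = 0.0714). All of these lists had passed camera in the same arrays before they were averaged. Tendon and synovial fibroblast markers, which had not passed (camera adjusted p = 0.0733 and 0.137), were left out. The p-values of these averages are therefore not independent evidence for the pattern. A smaller share of blood or marrow cells of every kind would lower erythroid markers alike. The neutrophil score moved against the erythroid score by -0.902 (exact permutation p = 0.0476, unadjusted), which over all arrays argues weakly against that as the whole source. The erythroid list held 7 measured genes and showed no difference of its own (exact permutation p = 0.730). Its test pointed lower without vehicle replicate 5 (median g = -0.087) or maslinic acid replicate 1 (-0.136), so this stays uncertain. With the neutrophil score as a covariate, the connective tissue difference was 0.853 (SE 0.326, exact permutation p = 0.00794, the smallest possible). Vehicle replicate 5 was the lowest vehicle array on the neutrophil score (-0.489) and the lowest of all arrays on collagens and matrix (-1.58). The fit was not repeated without it, and Mmp8 and Mmp9 stand in lists on both sides. Whether a smaller neutrophil share was the whole source of the connective tissue difference therefore stays open. The platelet difference went from -0.917 (SE 0.476) to 0.0175 (SE 0.380, exact permutation p = 0.984) with that covariate, and may go with the neutrophils. Vehicle replicates 3 and 5 stay open as a source of the connective tissue difference. Without them it was 0.337 (exact permutation p = 0.143), with the cartilage, osteoclast and protease calls lost. The neutrophil and platelet difference was -0.811 without them and -0.814 with all arrays (exact permutation p = 0.0714 for each). The neutrophil and platelet lists also kept their camera calls at the preset correlation. Among vehicle arrays, replicate 3 was highest on both scores (neutrophils 1.19, platelets 1.53) and replicate 5 lowest (-0.489 and -0.588). Leaving out both therefore cannot tell whether 1 of them was a source, and neither p was under 0.05. Replicates 3 and 5 stay open for the neutrophil and platelet difference too. Chance stays open too, as 7 of 100 splits of the arrays gave at least 15 lists and the highest other 19, and an effect of maslinic acid was not tested apart from these.

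Glucocorticoid receptor targets were higher with maslinic acid, and 3 of 100 splits, the real one included, gave a median g of at least 1.26 in size, with 1.37 the highest other. The other splits that reached this size (1.37 and 1.27) each shared 4 arrays with the real maslinic acid group. They are thus not independent of the real grouping. The list was singled out as the largest of 32 after its value was seen, and chance is not excluded for the largest of 32 list differences: 28 of 100 splits gave a difference of at least 3.13 standard errors, and the highest other gave 5.26. The list score varied opposite to the neutrophil score (Pearson r = -0.748, permutation p = 0.0123, adjusted 0.229 over 93 correlations; Spearman rho = -0.636, permutation p = 0.0539, adjusted 0.333; r = -0.680 without the 2 farthest arrays and -0.526 between deviations from the group means), and with that score as a covariate the difference went from 0.875 (SE 0.280) to 0.523 (SE 0.333, exact permutation p = 0.167), so a smaller neutrophil share cannot be told apart from a separate change. Another time of day at sacrifice is open as well: clock genes of one phase (5) minus those of the other (9) differed by 1.01, from -0.506 ± 0.955 to 0.506 ± 1.09 (SD, n = 5 each, exact permutation p = 0.175), and the labels give no hour. An effect of maslinic acid on the receptor or on corticosterone was not tested, since no hormone was measured.

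The first component carried most of the variation without separating the groups. A varying share of muscle in the dissected tissue is a candidate explanation, as Myh1 was among its leading genes, but the muscle score, which shares Myh1 and Mb with it, correlated with it at r = 0.471 (permutation p = 0.171), which leaves this open with 10 arrays. The severity of arthritis in each mouse is not in the labels, and no biological explanation was tested.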

How the results depend on the processing

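In limma 0 probe sets passed as deposited, with 3617 at an unadjusted p under 0.05, and 0 passed with the replicate number as a block, with trend and robust eBayes, and at a threshold of 0.1. The exact Wilcoxon test gave 0 as well, but its smallest p of 0.00794 left a pass all but impossible. Array weights gave 1, quantile normalization 8, the rank product 1576, and leaving out single arrays 0 to 1. At an unadjusted p under 0.05 there were 1864 above the median level, 2009 after quantile normalization, 737 after median centring, 1350 with 10 distinct values, and 2614 to 4579 without single arrays. With 10 distinct values 13104 probe sets were tested, and above the median level the upper 50%. In both the share at an unadjusted p under 0.05 was no smaller than the 9.04% of all probe sets, so these lower counts come from fewer tested. For the other counts the cause was not tested. Lists past the threshold numbered 15 (those that gained a call are named in the results), and 0 with an estimated correlation, in fry and after permuting arrays, 10 to 22 under the other settings, and 12 to 19 without single arrays. The group difference on the first component had an exact permutation p of 0.389 to 1 without single arrays. Glucocorticoid receptor targets kept their call except with an estimated correlation (adjusted p = 0.340), in fry (0.306) and after permuting arrays (0.127). The filters on 10 distinct values, list permutation, neutrophil covariate, unshared genes, most distinct values and leaving out vehicle replicates 3 and 5 were chosen after seeing the data. Floors for linear values did not apply. Array medians ranged over 0.000272, far above the spread of most probe sets, so median centring and quantile normalization impose shifts larger than that spread by construction.

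The direction of a gene is that of g, and the direction of a list that of its test, which can differ from the sign of its median g. Hedges' g of genes that reversed, and the median g of lists whose test reversed, follow. After quantile normalization Srprb was at -0.563, Rc3h1 -1.18, Smad4 -0.571, Slc38a2 -1.32, Sec23a -1.21, Atp7a -0.971, Zscan21 -0.294, Majin 0.0132, Fut7 0, Paqr5 0.361, Ptger2 0.0137, Sox9 -0.0967, Fzd4 -0.633, Irgm1 -1.13 and Nr3c1 -0.472, and the lists of acute-phase proteins at 0.338, oxidative phosphorylation -0.604, Nrf2 -0.551, neutrophils -0.394, macrophages 0.125, T and NK cells 0.0299 and Schwann cells 0.0549. After median centring Srprb was at -0.307, Rc3h1 -0.237, Smad4 -0.124, Eml1 -0.242, Slc38a2 -0.272, Sec23a -0.213, Abl2 -0.195, Atp7a -0.172 and Nr3c1 -0.179, and chemokines at -0.208, acute-phase proteins -0.0586, macrophages 0.132, skin -0.392 and Schwann cells -0.404. With the neutrophil covariate Mmp3 was at -0.519, cell cycle 0.70, Nrf2 0.0227, neutrophils 0.00175, T and NK cells 0.224, B cells 0.205, platelets 0.168, skin -0.190 and Schwann cells 0.245. With the muscle covariate chemokines were at 0.123, acute-phase proteins 0.250, oxidative phosphorylation -0.564, muscle 0.0490 and skin -0.163. With array weights Mmp3 was at -0.366 and Nrf2 at -0.0975, and without vehicle replicates 3 and 5 Mmp3 was at -0.198, Nrf2 -0.128 and endothelium -0.0465. Over genes with 10 distinct values oxidative phosphorylation was at 0.000466, Nrf2 -0.0310 and Schwann cells 0.369. As the mean of probe sets Nr3c1 was at -0.103, acute-phase proteins -0.0288 and skin -0.0649, and with the most distinct values acute-phase proteins were at -0.0288 and skin at -0.0788. With the block macrophages were at 0.144, above the median level skin at -0.531, in fry acute-phase proteins at -0.0288 and macrophages 0.193, and over unshared genes chemokines at 0.0168 and acute-phase proteins 0.251. Beyond the shifts imposed by normalization and the covariates' own removal, the cause was not tested.

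Median g also changed sign, with the test keeping its direction, for these lists. After median centring it was -0.180 for Toll-like receptor signalling, -0.153 TGF-beta and Wnt, -0.369 clock, -0.316 Nrf2, -0.159 endothelium and -0.351 oxidative phosphorylation. After quantile normalization it was -0.123 for TGF-beta and Wnt, -0.178 clock, -0.0860 endothelium and -0.143 chemokines. With array weights it was -0.0782 for Toll-like receptor signalling, -0.346 chemokines, -0.167 clock, -0.451 macrophages and -0.137 synovial fibroblasts, and with the neutrophil covariate -0.694 for chemokines and -0.540 macrophages. Without vehicle replicates 3 and 5 it was -0.156 for chemokines, -0.121 clock and -0.178 macrophages. It was 0.198 for mast cells with the muscle covariate, -0.0202 for Nrf2 as the mean of probe sets, 0.228 for acute-phase proteins and 0.0183 for mast cells over genes with 10 distinct values, and -0.000598 for chemokines with the block.

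Without single arrays the values that reversed, in g, median g or test, ranged from -0.121 to 0.675 for Nr3c1, -0.292 to 0.409 for Mmp3, -0.171 to 0.201 for acute-phase proteins, -0.116 to 0.443 for oxidative phosphorylation, -0.332 to 0.298 for macrophages, -0.0944 to 0.159 for skin, -0.451 to 0.283 for chemokines, -0.136 to 0.534 for erythroid cells, -0.471 to 0.0316 for Schwann cells, -0.350 to 0.191 for mast cells, -0.527 to 0.0669 for T and NK cells and -0.0525 to 0.392 for clock genes.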

Other observations

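The tests in this part were chosen after the results were seen. Genes named here were chosen after their values were seen.

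The second component, which was lower in the maslinic acid group, was led by Myh1 (16.9% of the component), Clec7a (12.8%), Serpina3n (12.5%), Ankrd1 (7.64%) and Trim63 (7.44%). Clec7a encodes dectin-1, a receptor of myeloid cells for fungal glucans, and had g = -1.48 (adjusted p = 0.549). Trim63 and Fbxo32 encode the muscle ubiquitin ligases MuRF1 and atrogin-1, which act in muscle atrophy and are induced by glucocorticoids. They had g = 1.22 (adjusted p = 0.585) and 1.30 (adjusted p = 0.579), so none of these genes passed.

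Over the 10 arrays, 93 correlations of the first component, the muscle score and the glucocorticoid receptor target score with list scores were computed, and 0 passed after adjustment. The first component was lower where the chemokine score was higher (Pearson r = -0.873, permutation p = 0.00157, adjusted 0.112; Spearman rho = -0.842, permutation p = 0.00392, adjusted 0.122; r = -0.795 without the 2 arrays farthest from the median). Part of this is by construction, since Ccl7 and Ccl2 of that list are among the component's leading genes. Pro-inflammatory cytokines, none of them among its 10 leading genes, gave Pearson r = -0.709 (permutation p = 0.0197, adjusted 0.261) and Spearman rho = -0.879 (permutation p = 0.00139, adjusted 0.0939), with r = -0.715 without the 2 farthest. The muscle score went with the oxidative phosphorylation score (Pearson r = 0.816, permutation p = 0.0024, adjusted 0.112; Spearman rho = 0.867, permutation p = 0.00202, adjusted 0.0939; r = 0.883 without the 2 arrays farthest from the median). Of 13 other marker lists, 8 correlated below 0 with the muscle score.

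Counts of probe sets were compared with those of 100 of the 126 splits of the arrays into 5 and 5. In limma 0 probe sets passed after adjustment and 3617 had an unadjusted p under 0.05. With a real count of 0 after adjustment, all 100 splits gave as many by construction, so that count tests nothing (highest other 4). At an unadjusted p under 0.05, 9 of 100 splits gave as many, with 5341 the highest other, and for the rank product 11 gave at least 1576, with 2226 the highest other. Chance is thus not excluded for the latter counts.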
